A study of Dreissena polymorpha with 10 samples.

How the data were processed

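The series holds 10 arrays of zebra mussels (Dreissena polymorpha, a freshwater bivalve) from Riba-Roja on the Ebro River, each hybridised with labelled RNA from part of the body, per the labels. The 6 season-by-sex groups were formed from the titles: June females, June males, September females and September males with 2 arrays each, and February females and February males with 1 array each. Per the labels' protocols, total RNA was extracted with Trizol, treated with DNase I, checked on a Bioanalyzer, and labelled with Cy3 for 1-colour Agilent arrays. The labels do not say how many animals went into an array, so p-values measure the spread between these arrays.

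Spot intensity values were extracted from the scans by the authors with Agilent Feature Extraction 10.5.1.1, per the file headers. The deposited processed signal is an intensity corrected for background within each array, with no scaling between arrays. The authors also deposited a table of log2 values with 15113 rows, in which 60 cells are empty and 95 non-control spots are missing. Each column of it was set against the log2 processed signal of the same array and correlated at 0.988 or higher, and column medians lay between 2.74 and 3.02. How the authors' log2 values were scaled and centred between arrays is not given in the sources used here, so that table served only as an alternative.

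Each array carried 15208 non-control spots and 536 control spots, which were left out. The non-control spots belong to 13654 probes, of which 12606 have 1 spot, 1026 have 2 spots and 22 have 25 spots, for 3541 transcript accessions or names. Log2 processed signals were averaged over the spots of a probe, leaving out spots flagged as non-uniform or as outliers where another spot remained. Probes were tested when well above background, by the scanner software's flag, on at least 2 of 10 arrays. This left 5139 probes of 2198 accessions, and 62.4% of probes were not tested. No spot was saturated.

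Each array was scaled by subtracting the 75th percentile of its log2 signals over the 2740 probes that were well above background on all 10 arrays. The design fixed before the data were examined took that percentile over all probes, with the detected probes as an alternative. The 2 were exchanged once under 50% of the probes proved to be above background, after looking at array signals and before any comparison was fitted. Counts under the scaling first planned are therefore printed beside the main ones. Values are called relative log2 signals below.

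A limma model (limma 3.58.1, R 4.3.3) with 1 mean for each of the 6 groups was fitted to all arrays, with 4 residual degrees of freedom and 1.65 prior degrees of freedom. All residual information comes from the June and September groups, so February arrays were assumed to vary like the others. That assumption could not be tested with 1 February array per sex. On February male replicate 1, spots of 1 probe scattered more than on the other arrays (SD of log2 signal 0.318 against 0.094 to 0.133). If that array varies more, the SEs and p-values of comparisons with February are too small. Season contrasts gave both sexes equal weight, and so do not depend on which February array is female. P-values were adjusted by Benjamini-Hochberg over the tested probes, with calls at an adjusted p under 0.05. A moderated F-test covered any season difference. Where a probe was not well above background on any array of a group, its fold is a lower bound, "at least N-fold". It sets the brighter group's mean against, per array, the higher of the probe's own signal and the lowest signal of any probe above background. Figures were drawn with matplotlib 3.10.9 (Python 3.11.15).

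The probes carry sequence accessions and no gene descriptions, apart from 6 probes named RXR. None of the accessions matched the RefSeq gene table of assembly UMN_Dpol_1.0 (0 matches), so no gene names or genome positions are given. For the same reason the 18 gene lists fixed in advance, with their set tests, were not tested. A planned check of the February sexes on probes that differ between the sexes was also not run, since no probe was called. The naming rule, for probes without names, allowed at most 2 accessions that rose and 2 that fell per comparison. These are the largest changes among called probes whose arrays did not overlap between seasons within either sex, taking the brightest probe of each accession.

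The fit was tested on simulated arrays with the real means and spreads of 5139 probes, 200 of them changed. A log2 change of 1 was recovered in 0% of changed probes in every comparison simulated. A log2 change of 2 was recovered in 56.9% of them for September against June, 25.4% for September against February and 25.3% for June against February. For females against males it was recovered in 0% within June or within September and in 55.7% over both. A log2 change of 3 was recovered in 61.9% for the June sexes, 61.8% for the September sexes and 77.5% for the sexes over both. The number of arrays limits the precision.

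Alternatives covered the background correction, the scaling between arrays, the authors' values, the filter on dim probes, the variance model, averaging of probes, the model terms, the replicate number, slide and scan date as blocks, swapped February sexes, a fold filter, and each array left out. Normexp background correction, planned on mean signals, used the median spot signal instead. A fit to the arrays of slide 1 alone was added after the data were examined.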

Results

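Transcript levels in zebra mussels were measured in February, June and September, which the series' design describes as the periods before spawning, of spawning and of gonad resorption. June and September had 4 arrays each, 2 per sex, and February had 2, 1 per sex. Mean signal per array was 8138 to 11000 on 9 arrays and 766.3 on September female replicate 2. Between 3945 and 4921 probes (28.9% to 36%) were well above background on those 9 arrays, against 3064 (22.4%) on September female replicate 2. Slide 1 held 8 arrays, while September male replicate 2 lay on slide 2 and September female replicate 2 on slide 3, and those 2 had another scan date. The 2 February arrays are female and male by title, and their descriptions name the opposite sexes.

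September arrays stood apart from those of the other seasons on the first principal component, and less clearly in pairwise correlations. Across the 5139 tested probes, which are not independent replicates, arrays of February and June correlated with each other at 0.947 to 0.974 (median 0.961, 15 pairs). September arrays correlated with them at 0.908 to 0.956 (median 0.931, 24 pairs) and with each other at 0.928 to 0.962 (median 0.942, 6 pairs). The last 2 ranges overlap: September female replicate 1 correlated at 0.956 with February female replicate 1 and at 0.941 with September female replicate 2. The first principal component held 29.9% of the variance. September arrays lay between 37.3 and 67.3 on it, and the other arrays between -48.9 and -22.9.

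**Figure D1:**
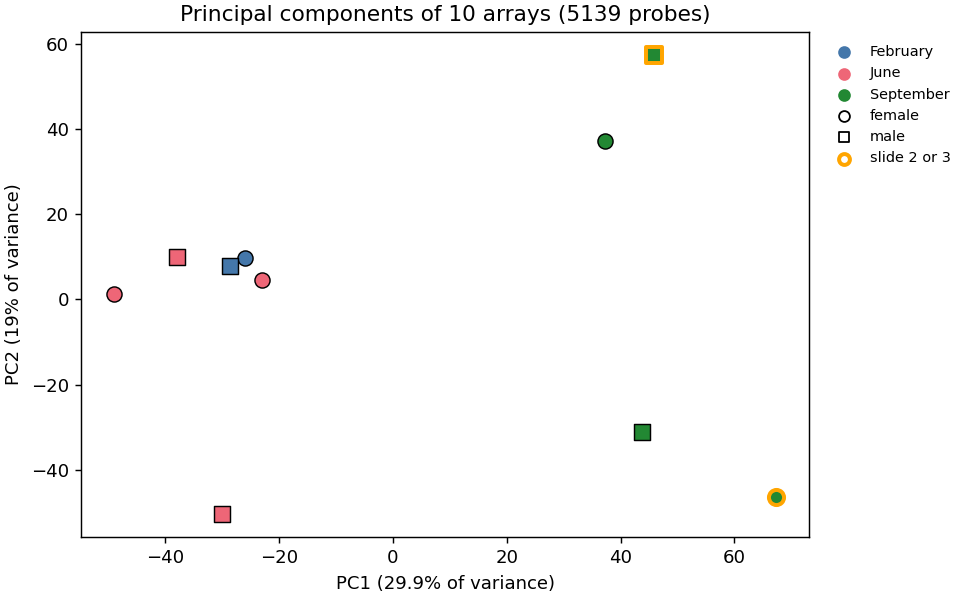
Scores of the 10 arrays on the first 2 principal components of the relative log2 signals, coloured by season, with circles for females and squares for males and an orange edge for the arrays on slides 2 and 3. The 4 September arrays lie at 37.3 or higher on the first component and the other 6 at -22.9 or lower.

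The season comparisons asked which transcripts differ between the sampling months. Reproductive stage cannot be told apart here from anything else that differed between those months. From June to September, the transcript EY434173 fell from a relative log2 signal of -2.99 ± 0.61 (SD, n = 4) to -11.3 ± 1.5 (SD, n = 4). Its log2 fold change was -8.33 (SE 0.426, adjusted p = 0.00147), both of its tested probes were called lower, and 1 of 4 September arrays was above background, so the size of the change rests largely on signals near background. EY434180 fell from -3.86 ± 0.42 (SD, n = 4) to -11.0 ± 0.72 (SD, n = 4), a log2 fold change of -7.13 (SE 0.42, adjusted p = 0.00173), with 5 of 5 probes called lower, and it was above background on 1 of 4 September arrays. EY434797 rose from -11.3 ± 0.89 (SD, n = 4) to -6.86 ± 0.86 (SD, n = 4), by 4.40 (SE 0.633, adjusted p = 0.0135), and was above background on 1 of 4 June arrays and 4 of 4 September arrays. EY435556 was above background on all 8 of these arrays and rose from -7.57 ± 1.8 to -3.25 ± 1.3 (SD, n = 4 each), by 4.31 (SE 0.942, adjusted p = 0.0385). In all, 715 probes of 384 accessions differed between September and June, 388 higher and 327 lower in September, with a median absolute log2 fold change of 1.82. Of those higher in September, 90 were not above background on any June array, and 38 of those lower were not above background on any September array. Of 634 called probes with another tested probe of their accession, 608 (95.9%) had the sign of the median of those probes, against 50.2% for randomly drawn probes. The random value used single probes in place of medians. Probes of an accession read the same RNA on the same arrays, so their agreement cannot tell season from an array effect.

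The numbers of higher and lower calls moved with the scaling, while all 715 probes kept their direction with the percentile over all probes and with quantile normalization. With the 75th percentile over all probes, as first planned, 290 probes were called, 114 higher and 176 lower. That scaling moved the median log2 fold change of all tested probes from 0.08 to -0.07. It shifts all probes alike, and the smallest called change was 0.746, so no called probe could turn direction under it. With slide as a block, 128 probes were called (26 higher and 102 lower), and with scan date as a block 261 (91 higher and 170 lower). All 715 kept their direction under either block, with a median log2 fold change in that direction of 1.65 against 1.82, but they were chosen on the same arrays, so this is no separate test. Slides 2 and 3 held 1 array each and made up the second scan date. Under either block the fold changes therefore rest on the slide 1 arrays alone. Normexp background correction called 86 and moved the median log2 fold change of all tested probes to 0.47. Under it 22 of the 715 probes turned direction, none of them called there, and the median in the main direction was 1.37. It gave smaller changes, -4.99 for EY434173 (adjusted p = 0.048), -4.16 for EY434180 (adjusted p = 0.059), 2.45 for EY434797 (adjusted p = 0.1) and 3.85 for EY435556 (adjusted p = 0.078). EY434797 was called in 22 of 27 alternatives, losing the call among others with the slide block (3.74, adjusted p = 0.09), without June female replicate 1 (4.31, adjusted p = 0.064) and without September male replicate 2 (4.21, adjusted p = 0.056). EY435556 was called in 16 of 28 and lost the call with the slide block (3.62, adjusted p = 0.18) and the scan date block (3.62, adjusted p = 0.16). It also lost it without June female replicate 1 (3.60), June male replicate 1 (3.80), June male replicate 2 (4.83), September female replicate 2 (3.65), September male replicate 1 (4.34) or September male replicate 2 (4.29), at adjusted p-values of 0.081 to 0.11. Within the 8 arrays of slide 1, fitted with additive season and sex as an alternative chosen after the data were seen, 563 were called (249 higher and 314 lower), against 955 with that model on all arrays. Slide 1 alone and the 2 blocks gave the same fold changes (3.74 for EY434797, 3.62 for EY435556). Their counts differ only through the estimate of the spread and its degrees of freedom. Counts fell to 144 without June female replicate 1, 414 without June female replicate 2, 224 without June male replicate 1 and 213 without June male replicate 2. They fell to 404 without September male replicate 1 and 206 without September male replicate 2. Without the dim array, September female replicate 2, there were 551.

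**Figure D2:**
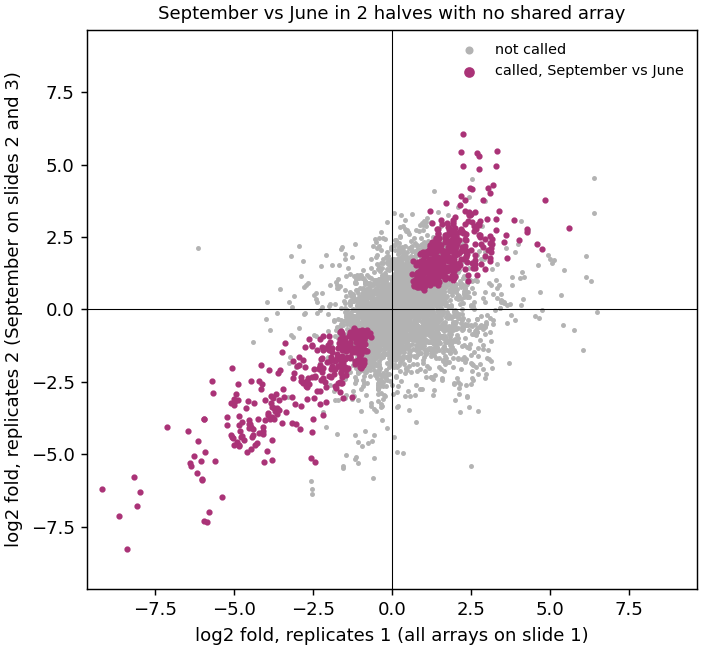
Log2 fold changes of September against June for each tested probe, from replicates 1 (x axis, all on slide 1) and from replicates 2 (y axis, September arrays on slides 2 and 3), which share no array. Probes called in the comparison of all arrays are purple and the others grey; over all tested probes r was 0.555, and because the calls were made on the same arrays their position alone is no separate test.

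Between February and June, called probes were mostly higher in June. EY434180, which fell again by September, rose from -10.5 ± 2.6 (SD, n = 2) to -3.86 ± 0.42 (SD, n = 4). Its log2 fold change was 6.65 (SE 0.514, adjusted p = 0.0106) and 5 of 5 probes were called higher, with 1 of the 2 February arrays above background. The 2 February arrays differed widely for it, at -12.4 in the array titled female and -8.64 in that titled male, a spread that the SE does not include. Its log2 fold change was 5.05 (adjusted p = 0.14) without February female replicate 1 and 8.25 (adjusted p = 0.028) without February male replicate 1. EY433996 rose from -9.76 ± 2.4 (SD, n = 2) to -3.54 ± 0.46 (SD, n = 4), by 6.22 (SE 0.218, adjusted p = 0.00131), with 1 of 2 February arrays above background. Its SE does not include the spread between those arrays either (-11.5 and -8.07), and the change was 4.93 (adjusted p = 0.033) and 7.51 (adjusted p = 0.0032) without the one or the other. EY436769 was above background on both February arrays and on none of the 4 June arrays, at least 20.4-fold lower in June (adjusted p = 0.0259). Only 1 of its 2 tested probes was called, and the other had a log2 fold change of -0.196. EY435953 fell by 2.25 on the log2 scale (SE 0.293, adjusted p = 0.04). In all, 54 probes of 30 accessions were called, 51 higher and 3 lower in June, with a median absolute log2 fold change of 3.32. The 51 probes that rose had a median of 0.685 for the February array titled male minus that titled female, against -0.08 over all tested probes, and 37 of the 51 were higher in the array titled male.

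The 75th percentile over all probes called 8 probes (7 higher and 1 lower in June), quantile normalization 19 (15 and 4), the authors' values 22 (18 and 4) and the slide block 9 (7 and 2). All February and June arrays lie on slide 1, so the slide block left these fold changes as they were, at 6.65 for EY434180. It changed only the estimate of the spread, and leaving out a September array does the same. Within slide 1, with additive season and sex, 84 were called (76 and 8), against 65 with that model on all arrays. The count was 1 without February female replicate 1, June female replicate 1, June male replicate 1 or June male replicate 2, 4 without June female replicate 2, 12 without February male replicate 1, and 18 without September male replicate 1 or September male replicate 2. Normexp background correction called 0 probes, with 229 at an unadjusted p under 0.05 against 522 in the main setting, and gave 4.92 for EY434180 and 4.33 for EY433996 (adjusted p = 0.44 each), -3.1 for EY436769 (adjusted p = 0.83), which is less than the bound above, and -2.01 for EY435953 (adjusted p = 0.53). Over all alternatives EY433996 was called in 25 of 26, EY434180 in 18 of 26, EY436769 in 13 of 26 and EY435953 in 10 of 27.

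Between February and September, EY435962 rose at least 45.2-fold (adjusted p = 0.0244) and EY434967 at least 33-fold (adjusted p = 0.0154). Neither was above background on the 2 February arrays, both were on 4 of 4 September arrays, and all 3 probes of the former and all 4 of the latter were called higher. The 4 probes of EY434967 had log2 fold changes of 2.78 to 5.53, so its bound is that of 1 probe. Its adjusted p does not include the spread between the 2 February arrays (-11.9 and -10.2). AF508224 fell from 1.95 ± 1.2 (SD, n = 2) to -3.04 ± 0.95 (SD, n = 4). Its log2 fold change was -4.99 (SE 0.522, adjusted p = 0.017), with 4 of 5 probes called lower and the 5 ranging from -5.03 to -0.913. The SE does not include the spread between the 2 February arrays (1.1 in that titled female and 2.79 in that titled male). EY436769 fell by 4.07 on the log2 scale (SE 0.493, adjusted p = 0.0205), and its other tested probe gave 0.254. In all, 378 probes of 219 accessions were called, 248 higher and 130 lower in September, with a median absolute log2 fold change of 2.37. The median log2 fold change of all tested probes was 0.21.

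The numbers of higher and lower calls again moved with the scaling, while all 378 probes kept their direction with the 75th percentile over all probes and with quantile normalization. The percentile shifts all probes alike, by less than the smallest called change of 1.08, so no called probe could turn under it. The 75th percentile over all probes called 87 (33 higher and 54 lower, median of all probes -0.26), quantile normalization 206 (93 and 113), and the authors' values 294 (157 and 137). With replicate number, scan date or slide as a block 0 probes were called, with 1044, 1085 and 1224 at an unadjusted p under 0.05 in limma against 1303 in the main setting. All 378, chosen on the same arrays, kept their direction, with a median log2 fold change in that direction of 2.27, 2.26 and 2.26 against 2.37. Under the scan date or slide block these changes rest on the slide 1 arrays alone. Normexp called 14 and moved the median of all tested probes from 0.21 to 0.56. Under it 5 of the 378 turned direction, none of them called there. It gave 3.46 for EY435962 (adjusted p = 0.14) and 3.9 for EY434967 (adjusted p = 0.037), both less than the bounds above, and -2.18 for EY436769 (adjusted p = 0.32). EY435962 had 5.06 (adjusted p = 0.029) without September female replicate 2, and 4.84 with the slide block (adjusted p = 0.09) or the scan date block (adjusted p = 0.066), also below its bound. It was likewise below it with quantile normalization (5.42), the percentile over all probes (5.35) and the replicate block (5.25). EY434967 had a log2 fold change of 4.39 without February female replicate 1 and 4.97 with quantile normalization, also below its bound. Over all alternatives EY435962 was called in 12 of 26, EY434967 in 17 of 26, AF508224 in 17 of 27 and EY436769 in 14 of 26. Leaving out a June array left these fold changes as they were (5.81 for EY435962, 5.53 for EY434967) and changed only the estimate of the spread. Within slide 1, with additive season and sex, 379 were called (245 higher and 134 lower), against 671 with that model on all arrays. The count was also 0 without February female replicate 1, February male replicate 1, June male replicate 1, June male replicate 2 or September male replicate 2. It was 13 without September male replicate 1 and 144 without June female replicate 1 or June female replicate 2.

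**Figure D3:**
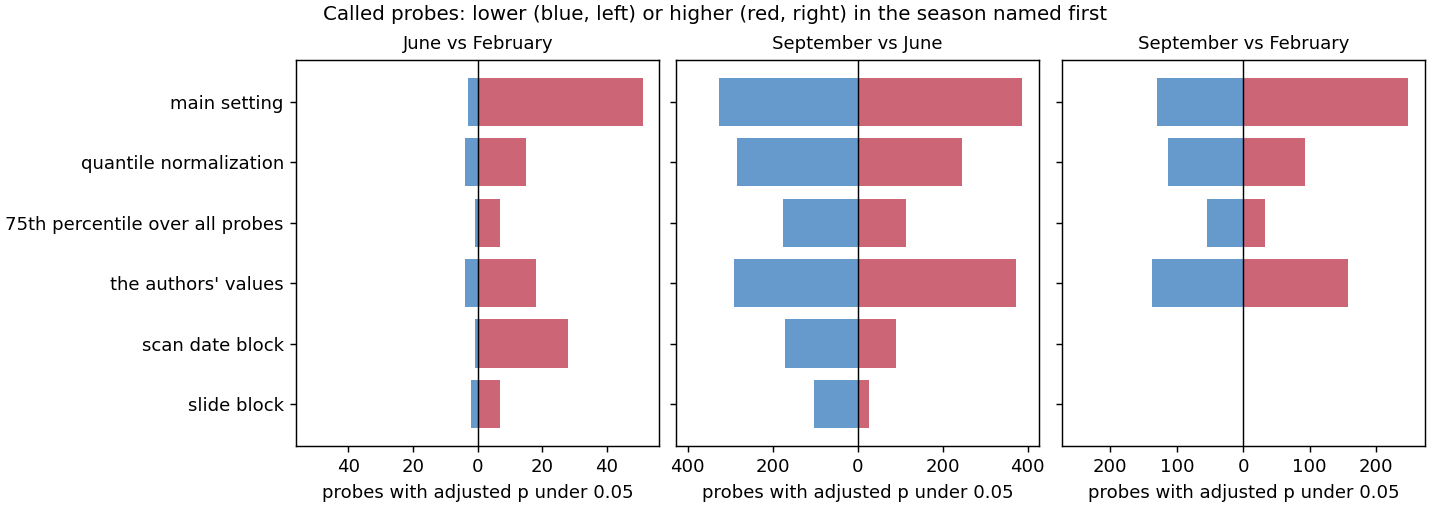
Probes with an adjusted p under 0.05 in each season comparison, lower (blue, to the left) or higher (red, to the right) in the season named first, for the main setting and 5 alternatives. September against June ranges from 128 calls with the slide block to 715 in the main setting, and September against February has 0 calls with either block.

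**Figure D4:**
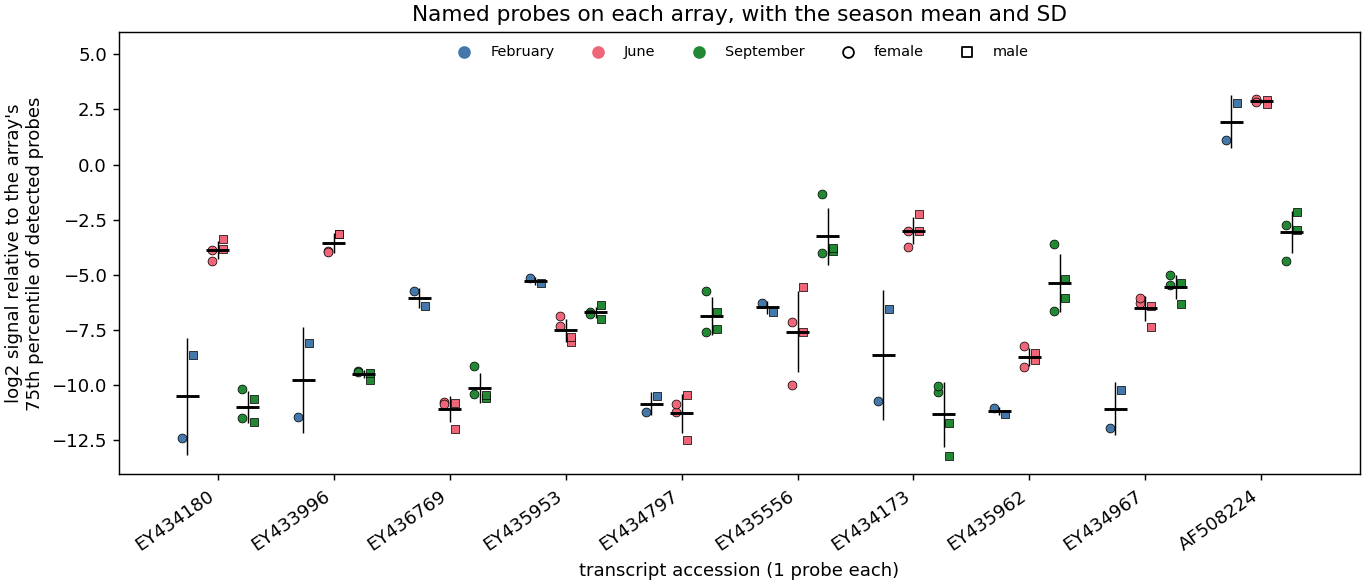
Relative log2 signal (y axis) of the 10 named transcripts on each array, 1 probe each, coloured by season with circles for females and squares for males. Horizontal bars are season means and vertical lines 1 SD (2 February, 4 June and 4 September arrays); EY434180 lies at -3.86 in June and near -11.0 in September.

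A moderated F-test found a difference between any seasons for 564 probes of 313 accessions. September was the season farthest from the mean of the 3 season means in 418 of them (74.1%), against 49.2% of all tested probes. By the season farthest from that mean, September lay above it in 261 probes and below it in 157 (46.3% and 27.8% of the called, against 29.9% and 19.3% of all tested). June was farthest and above in 80 (14.2%, against 11.1% of all tested) and below in 10 (1.77% against 9.73%). February was farthest and above in 9 (1.6% against 11.9%) and below in 47 (8.33% against 18.1%). With the 75th percentile over all probes 196 were called, and 14 with the slide block. The division into above and below is that of the main scaling and depends on it. With the percentile over all probes, September calls were mostly lower, with 114 higher and 176 lower against June. Against February they were 33 higher and 54 lower. Leaving out 1 array gave 146 without February female replicate 1, 100 without February male replicate 1, 167 without June female replicate 1, 264 without June female replicate 2, 159 without June male replicate 1, 149 without June male replicate 2, 373 without September female replicate 2, 180 without September male replicate 1 and 103 without September male replicate 2.

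Calls were shared between comparisons. The lists set against each other here are not independent, even where arrays were divided between them. The calls used the spread estimated from all arrays, so a probe with a small estimated spread is favoured in both lists. Probes of an accession were also counted singly. Sharing above the value for independent lists is therefore no separate test of the changes. Of the 51 probes higher in June than in February and the 327 lower in September than in June, 39 were the same, of 20 accessions. Independent lists of those sizes would share 3.25. Both comparisons use the June arrays, and with these divided between them 15 and 10 probes were shared, against 0.504 and 0.396 for independent lists. Simulations without any change shared 0, but made too few calls (0.07 and 0.03 on average) to give a chance value for lists of these sizes. The lists of September against June and against February shared 293 probes changed in the same direction, of 168 accessions, against 27 for independent lists. With the September arrays divided between them, in either of 2 ways, at least 50 were shared, against 5.67 and 2.8 for independent lists.

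Females and males were compared within June, within September and over both. limma called 0 probes in each of the 3 comparisons, with 257, 199 and 259 probes at an unadjusted p under 0.05 and smallest adjusted p-values of 0.531, 0.924 and 0.919. The interaction of sex with season also gave 0 calls (238 at an unadjusted p under 0.05, smallest adjusted p = 0.823). The probe with the smallest p among those higher in June females was of EY434408, at -8.77 ± 0.19 in females and -11.9 ± 0.11 in males (SD, n = 2 each, adjusted p = 0.531). Among those higher in June males it was of EY435654, at -12.6 ± 0.2 in females and -10.9 ± 0.47 in males (SD, n = 2 each, adjusted p = 0.544). In September the probe higher in females was of AM230100, at -6.42 ± 0.06 in females and -10.8 ± 0.19 in males (SD, n = 2 each, adjusted p = 0.924), and that higher in males of EY436961, at -4.67 ± 0.083 and -3.39 ± 0.077 (SD, n = 2 each, adjusted p = 0.924). Signals of -10.8 or lower lie near those of EY436769 in June (-11.1, above background on 0 of 4 arrays) and EY434180 in September (-11.0, 1 of 4). The differences for EY434408, EY435654 and AM230100 therefore rest in part on signals near background. In simulation, a log2 change of 2 was recovered in 0% of changed probes within a season and in 55.7% over both. With 200 probes changed, differences of that size were thus missed within June or within September, and found in part over both. The share recovered depends on how many probes change, so it is no fixed limit of detection. For September against June the simulation recovered 0% at a log2 change of 1, while real calls went down to 0.746. The slide block called 7 probes in June, and single arrays left out gave up to 4 in June (without September male replicate 1 or 2), 16 in September (without September female replicate 1) and 4 over both (without September male replicate 1). All June arrays lie on slide 1. The slide block, or the loss of a September array, therefore changed only the estimated spread of the June comparison. The February sexes had 1 array each and were not tested.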

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

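The tests of slide or scan date, of the dim array and of the February labels were chosen after the results were seen. Among 6 measures of array quality over the 10 arrays, 4 single values stood farther from the rest than Dixon's 95% critical value, which chance passes in about 5% of groups. September female replicate 2 had a mean signal of 766.3, against 8138 to 11000 on the other arrays. Its brightest spike-in probe read 5993.5, against 94593 to 176100, and 3064 of its probes were well above background. Its background of 24 lay within the range of 18 to 27 of all arrays. On February male replicate 1, the SD of log2 signal between the 25 spots of a probe was 0.318 (median of 10 probes), against 0.094 to 0.133 on the others.

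September differed from June in 715 probes. Slide or scan date as the whole cause is argued against by fold changes that correlated at 0.555 between replicates 1, all on slide 1, and replicates 2 (0.47 with the June replicates exchanged), above the highest of 0.342 between replicate differences; these r are across genes, which are not independent. The floor of the dim array as the whole cause is argued against by 551 calls without it, and chance by 1 of 100 regroupings of the arrays reaching 715 (the real one; the highest other gave 2). Of 150 probes called from replicates 2, all 150 had the same direction in replicates 1, against 65.9% of all tested probes. Those calls used the spread estimated from all arrays, replicates 1 among them, so this is no separate test. A part from slide stays open. With slide as a block, which takes away 2 of 4 residual degrees of freedom, 128 probes were called. With additive season and sex, slide 1 alone gave 563 and all arrays 955. The slide block and slide 1 alone gave the same fold changes, so 128 against 563 does not bear on slide. Season, as spawning against gonad resorption, may account for the difference as a hypothesis, but anything else that differed between the sampling months was not tested.

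The February titles and descriptions name opposite sexes, while the names of the scanner files carry the sexes of the titles. If the titles were swapped, and if the June difference between females and males reflects sex, the February difference (titled female minus titled male) should run against it. Across probes the 2 correlated at 0.299, above the 0.197 of the higher of the other 2 splits of the June arrays, and at 0.442 against 0.115 over probes above background on all arrays. Neither value can decide on a swap. The June and September differences between females and males correlated at -0.00074 over all tested probes. Over probes above background on all arrays they correlated at -0.102. The June difference was thus not shared by September and is no established mark of sex. The reading was also made more cautious once the 0.299 had been seen: with 3 splits no share under 0.05 is possible. No probe differed between the sexes at an adjusted p under 0.05, and the February difference correlated with that of the September sexes at 0.052. The swap therefore stays open, and the season comparisons do not depend on it.

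The wide spread between spots on February male replicate 1 was set against 2 technical explanations. A gradient across the array is argued against by row and column explaining 2.45% of the variance between spots, below the highest other array at 4.32%. A few deviating spots as the whole cause are argued against by a spread from the median absolute deviation of 0.171, above the highest other at 0.097. No biological explanation was tested, since the spots of a probe share 1 sample.

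For females against males over June and September, the real groups gave 0 calls, which all 100 of 100 regroupings reach by construction, so the regroupings say nothing about chance. The highest regrouping gave 546 calls and points to a structure of the samples. It set the 4 September arrays against 2 June and 2 February arrays. For June against February, 1 of 100 regroupings reached 54 calls (the highest other gave 17). For September against February, 3 of 100 reached 378, the highest other with 686, which set 2 September arrays against 3 June arrays and 1 February array.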

How the results depend on the processing

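Of 319 values of the named transcripts under alternatives, 217 kept their direction and their call, 102 lost the call and 0 reversed. The fall of EY434173 from June to September was called in all 27 alternatives that gave a value, but its log2 fold change ranged from -8.71 to -4.99, the smallest with normexp. EY435953 from February to June was called in 10 of 27. All counts were within 1.5 times the main ones with trended and robust variance, probes above background on all arrays, the June and September arrays only, swapped February sexes and a log2 fold of at least 1. Unless a cause is given, the cause was not tested.

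For June against February (54 in the main setting), counts were 0 with normexp, 19 with quantile normalization, 29 with the median in place of the percentile, 8 with the percentile over all probes, 22 with the authors' values, 5 with no filter on dim probes, 13 without moderation of the variance, 21 with probes of an accession averaged, 29 with the scan date block and 9 with the slide block. The 8 arrays of slide 1 alone, with additive season and sex, an alternative chosen after the data were seen, gave 84. All February and June arrays share slide 1 and a scan date, so both blocks changed the estimate of the spread and not the fold changes.

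For September against June (715), they were 86 with normexp, 290 with the percentile over all probes, 122 with no filter, 247 with probes averaged, 261 with the scan date block and 128 with the slide block.

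For September against February (378), they were 14 with normexp, 206 with quantile normalization, 87 with the percentile over all probes, 0 with no filter, 143 without moderation, 117 with probes averaged, 671 with additive season and sex, 691 with season alone, 0 with the scan date block and 0 with the slide block.

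For any season difference (564), they were 43 with normexp, 352 with quantile normalization, 196 with the percentile over all probes, 73 with no filter, 324 without moderation, 200 with probes averaged, 922 with additive season and sex, 959 with season alone, 133 with the scan date block and 14 with the slide block. Females against males in June gave 7 with the slide block. Averaging tests 2198 accessions in place of 5139 probes, and the slide block takes away 2 of the 4 residual degrees of freedom.

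Replicate numbers did not pair the arrays, since replicate differences of the groups correlated at -0.327 to 0.342. With the replicate block the counts were 6 for June against February, 0 for September against February and 347 for any season difference, and no other count moved by over 1.5 times.

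With each array left out in turn, where an array left alone in its group was assumed to vary like the others, counts ranged from 1 to 36 for June against February, 144 to 934 for September against June, 0 to 560 for September against February and 100 to 713 for any season difference. They ranged from 0 to 4 for the sexes in June, 0 to 16 in September, 0 to 4 over both, and were 0 for the interaction. The gene lists and the check of the February sexes were not run, for want of gene names and of called probes. Signal over background limits the dim probes: 62.4% of all probes were not tested.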

Other observations

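The only probes with a gene name were the 6 named RXR, looked up after the data were seen. Of these, 2 were tested, each above background on 6 of 10 arrays (2 of 2 in February, 1 of 4 in June and 3 of 4 in September). Their log2 values for September minus June were 0.39 (SE 0.28, adjusted p = 0.44) and 0.95 (SE 0.38, adjusted p = 0.16), and for June minus February -0.56 (adjusted p = 0.73) and -0.91 (adjusted p = 0.63), so neither passed the test.

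Probes of 1 accession often differed in whether they were measurable. Of 3306 accessions with at least 2 probes, 712 had all of them tested, 1358 some and 1236 none.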
